A study of Mus musculus with 2 samples.

How the data were processed

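RNA was sequenced from the pleuroperitoneal folds (PPFs) of wild-type mouse embryos at embryonic day 12.5, in 2 libraries that the labels call biological replicates 1 and 2 of a single group. PPFs are paired embryonic folds from which connective tissue of the diaphragm arises. Per the labels, the mice were of mixed 129 and C57BL/6 background, each library pooled 2 PPF pairs, the heart and lungs were removed before the folds were dissected by hand, and libraries were prepared from polyadenylated RNA with a stranded kit. Whether the pairs came from separate litters is not given in the sources used here.

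Per the submitters' processing notes, the authors used STAR 2.4.0a, SAMtools 1.3 and featureCounts and named the genome build mm9. The deposited coordinates were compared with the GENCODE M21 annotation of GRCm38: of the symbols found in both, 77.5% (27675) had an identical chromosome, start and end, so positions are given here as GRCm38. The strand setting of the counting step is not given in the sources used here. Each file listed 38926 gene symbols with a raw count, which the authors left unnormalised, and a TPM value (count per base of gene length, scaled to the same sum in each library), which the authors computed. The deposited TPM equalled count divided by gene length, scaled to a fixed sum, with a largest difference of 4.7e-11. The deposited counts summed to 26370253 in replicate 1 and 23255957 in replicate 2. A gene with 0 counts could hold up to 0.114 CPM (counts scaled to the library total) in replicate 1 and 0.129 in replicate 2, from a floor of 3 counts. All intervals and floors cover counting error only, because no spread between libraries or animals enters them. Reads without molecular identifiers are not independent molecules, so even the counting error can be larger than the intervals show.

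Features shorter than 200 bp (5877 of those listed) held 10.5% and 10.4% of the TPM in replicates 1 and 2 but 0.281% and 0.271% of the counts. Many lie inside exons of longer genes. Among features nested in exons of a host gene with at least 1000 counts, the median count per base relative to the host was 0.275 for the 48 on the opposite strand and 0.266 for the 125 on the same strand, so reads were assigned to overlapping features on either strand. Levels of genes that share exon bases with a neighbour therefore can include reads of that neighbour. Biotypes came from GENCODE and RefSeq symbols, and 21446 symbols were protein-coding.

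A gene was called expressed at 1 TPM or more in both libraries. Before the data were examined, 28 gene lists were fixed: 3 of genes linked to congenital diaphragmatic hernia (CDH) in humans or mice, from general knowledge, and 25 of cell types, pathways and controls. With the union of the CDH lists, 29 lists were described. Members not found in the files were not analysed here, which left 38 of 39 Hox genes, 22 of 25 erythroid, 23 of 24 neuronal and 20 of 21 cartilage, tendon and sclerotome genes. For each list the median of log2(TPM + 1) was placed among 10000 random lists of the same size, drawn from protein-coding genes matched on decile of gene length. Between the libraries, the log2 ratio of replicate 2 to replicate 1 was computed per gene from counts plus 0.5, scaled by TMM factors from edgeR 4.0.16 (1.0011 and 0.9989). An exact two-sided binomial test of the counts with Benjamini-Hochberg adjustment was run on 19433 genes with at least 10 counts over both libraries, and a gene was counted as different at an adjusted p under 0.05 and a ratio of at least 2-fold. This test compares these 2 libraries, not conditions or animals, and treats counting error as the only noise. The median ratio of each list was placed among 10000 random lists matched on decile of mean CPM. The edgeR common dispersion was fitted with an intercept alone.

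The rule for naming genes, fixed at the same time, took the 4 highest and 2 lowest members of each list by mean TPM, 20 core PPF genes, the 15 features with the highest TPM, the 10 highest and 10 lowest ratios among genes with adjusted p under 0.05, at least 100 counts and a mean of at least 1 TPM, and up to 3 members of each list with the largest ratio in size. Named outside this rule, after their values were seen, were the 25 nuclear protein-coding genes with the highest TPM, Hoxa7, Hoxa9 and Hoxb9, and the genes named under the additional observations.

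Counts were simulated with 200 changed genes, drawn from those with at least 100 counts over both libraries. Detection of changes in genes with fewer counts was not simulated. With sampling noise alone, the test called 96.5% of genes changed 2.5-fold, and 1 unchanged gene, while a 4-fold change gave 100% and 5 unchanged genes. With the spread that edgeR estimated added, it called 94.0% and 100%, together with 41 and 39 unchanged genes past 2-fold, and 4403 and 4413 unchanged genes had an adjusted p under 0.05. Of 200 random lists placed by level, 1.5% lay above the 97.5th percentile and 2.5% below the 2.5th. The percentiles of list ratios between the libraries were not checked in this way.

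Alternatives fixed at the outset were thresholds of 0.5 and 5 TPM, 1 CPM and 10 counts, other backgrounds and no matching for the random lists, log2(CPM + 1), a pseudocount of 0.1, leaving out each replicate, library size alone and DESeq2 1.42.0 size factors in place of TMM, no count filter or a minimum of 100 counts, and 1.5-fold and 3-fold thresholds. Chosen after seeing the data were TPM rescaled without features under 200 bp, leaving out CDH genes that share over 25% of their exon bases, leaving out short features and pseudogenes from the genes that differed, random lists matched on 5 bins of gene length and 5 of CPM, and ratios corrected by a polynomial in gene length and GC content. Copies of genes were sought with BLAST 2.17.0 among annotated transcripts. Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. With a single group there was no comparison between conditions, and no correlation across samples was computed.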

Results

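Messenger RNA levels were measured in the PPFs of wild-type mouse embryos at embryonic day 12.5 in a single group of 2 libraries, replicates 1 and 2, each from 2 pooled PPF pairs. The total counts were 26370253 in replicate 1 and 23255957 in replicate 2, and 24412 and 24221 of the 38926 listed genes had at least 1 count. Values are means ± SD with n = 2 unless stated, and the series holds no other tissue, stage or genotype to compare with.

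The 25 nuclear protein-coding genes with the highest TPM held Hsp90ab1, a chaperone gene (3135 ± 7.13 TPM), and the translation genes Rplp1 (3031 ± 319 TPM), Rpl8 (2962 ± 208 TPM), Rpl4 (2717 ± 7.005 TPM), Eef1a1 (2553 ± 52.0 TPM), Eef2 (2397 ± 45.9 TPM) and Rps15 (1581 ± 85.4 TPM). Hbb-y, an embryonic globin, stood at 4283 ± 253 TPM, and the imprinted growth factor gene Igf2 at 3459 ± 47.3 TPM. The fibrillar collagen genes Col1a1 and Col3a1 reached 2810 ± 16.9 and 2521 ± 19.9 TPM, and the cardiac actin gene Actc1, which embryonic skeletal muscle also uses, 1924 ± 64.9 TPM. Other genes among the 25 highest were the imprinted Cdkn1c (2334 ± 26.3 TPM) and Mest (1925 ± 46.1 TPM), the growth factor genes Ptn (2347 ± 143 TPM) and Mdk (1708 ± 177 TPM), and Gpc3 (1526 ± 93.3 TPM), a glypican gene. The imprinted noncoding RNA H19 stood at 12622 ± 92.8 TPM and held 0.968% and 0.931% of the counts in replicates 1 and 2. Mitochondrial genes, led by mt-Cytb at 12063 ± 49.8 TPM and mt-Nd1 at 10801 ± 916 TPM, held 1.67% and 1.72% of the counts. The features H19_2, Mir675, H19_1, Gm26377 and Gm22133 were also among the 15 highest by TPM; Mir675 lies entirely in H19 exons, Gm26377 in Eef1a1 and Gm22133 in Ftl1. Igf2 shares 64.5% of its exon bases with other annotated genes, Cdkn1c 30.7%, and Gm20721, at 3347 ± 17.8 TPM, shares 99.0% with Gnas.

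Expressed in both libraries were 17273 of the listed genes and 13590 of the 21446 protein-coding genes (63.4%). The expressed protein-coding genes had a median of 26.8 TPM. Of these, 3506 had a mean of 1 to 10 TPM, 8301 of 10 to 100 TPM, 1733 of 100 to 1000 TPM and 50 of 1000 TPM or more. Across expressed protein-coding genes, which are not independent replicates, the libraries had a Pearson r of 0.994 on log2(TPM + 1) and a Spearman rho of 0.995. The median coefficient of variation between the libraries was 5.09%, and 97.2% of these genes differed by less than 1.5-fold.

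**Figure D1:**
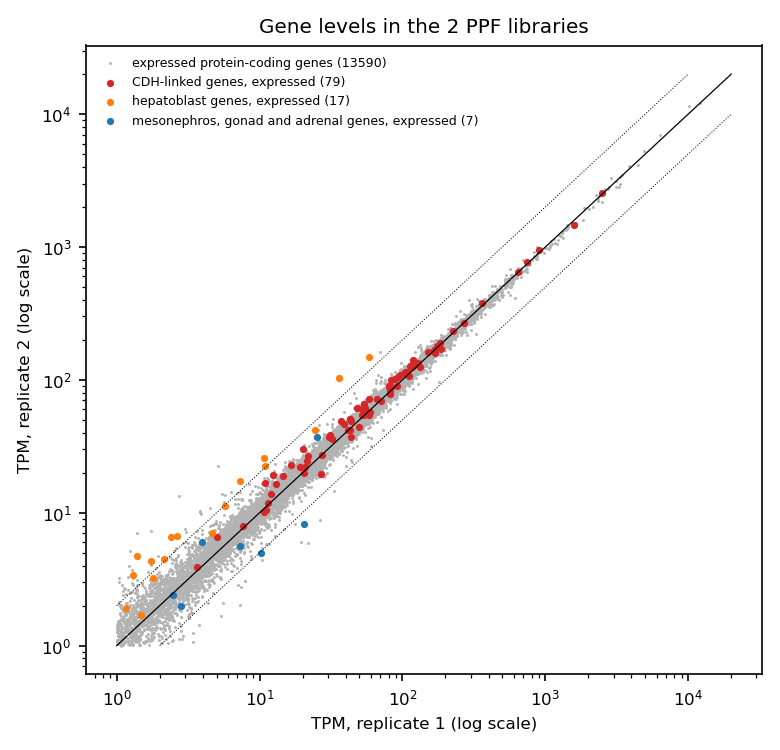
TPM of the 13590 expressed protein-coding genes in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), with the expressed members of 3 lists coloured; the solid line marks equal values and the dotted lines 2-fold differences. The 79 expressed CDH-linked genes lie within the dotted lines, and hepatoblast genes lie above the solid line.

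The purpose the series states is to rank genes implicated by human studies of CDH, a birth defect in which the diaphragm does not close, by their expression at this stage. The CDH-linked genes used here were instead listed from general knowledge of humans or mice, so their order is not the series' own ranking. Of the 80 CDH-linked genes, 79 were expressed in both libraries and 76 had at least 10 TPM in both. Their median level was 58.2 ± 3.72 TPM. Transcription and chromatin regulators were all expressed (38 of 38), as were the matrix, adhesion and cytoskeleton genes (14 of 14), and of the signalling and retinoid genes 27 of 28. The one without a count was Shh, a secreted Hedgehog ligand, for which 0 counts in both libraries allow up to 0.153 TPM.

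Among the transcription and chromatin regulators the highest were Myog, a myogenic regulator, at 648 ± 0.661 TPM, the chromatin remodeller gene Smarca4 at 229 ± 3.31 TPM, Myod1 at 179 ± 10.003 TPM and Gata4 at 176 ± 3.50 TPM. The lowest were Tcf21 at 10.5 ± 0.474 TPM and Pax3, a gene of migrating muscle progenitors, at 3.77 ± 0.165 TPM. The signalling and retinoid genes were led by Ctnnb1, the beta-catenin gene, at 919 ± 30.9 TPM, Pdgfra at 368 ± 11.9 TPM, Aldh1a2, which encodes a retinoic acid synthesising enzyme, at 269 ± 0.431 TPM and Fzd2 at 165 ± 6.40 TPM, and above Shh the lowest was Lrp2 at 5.81 ± 1.04 TPM. The matrix genes were led by Col3a1, Gpc3, Flna at 759 ± 16.9 TPM and Lox, a collagen cross-linking enzyme gene, at 186 ± 4.72 TPM, and the lowest were Frem1 at 42.8 ± 8.19 TPM and Dsel at 23.04 ± 2.05 TPM.

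Core PPF genes are given with their GRCm38 positions. Wt1 (chromosome 2, 105126529 to 105173612) stood at 90.7 ± 1.33 TPM, Gata4 (chromosome 14, 63198922 to 63245271) at the level above, its cofactor gene Zfpm2 (chromosome 15, 40655042 to 41104592) at 42.6 ± 5.01 TPM and Nr2f2 (chromosome 7, 70351946 to 70360593) at 56.8 ± 3.51 TPM. Tbx5 (chromosome 5, 119834663 to 119885218) stood at 46.8 ± 5.54 TPM, Osr1 (chromosome 12, 9574442 to 9581499) at 130 ± 8.74 TPM and Tcf7l2 (chromosome 19, 55741810 to 55933654), a marker of muscle connective tissue fibroblasts, at 22.4 ± 0.384 TPM. Rarb, a retinoic acid receptor gene (chromosome 14, 16430842 to 16575472), stood at 69.8 ± 1.17 TPM and shares 38.4% of its exon bases with other annotated genes, Top2b among them. Pdgfra lies on chromosome 5 (75152291 to 75198204) and Aldh1a2 on chromosome 9 (71215789 to 71296243). Robo1 (chromosome 16, 72663149 to 73046095), the gene of a Slit receptor, stood at 129 ± 15.8 TPM and the ligand gene Slit3 (chromosome 11, 35121224 to 35708507) at 25.1 ± 7.04 TPM.

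The muscle progenitor genes Pax3, Pax7, Lbx1, Myf5 and Met stood below Myod1 and Myog in both libraries. Pax3 (chromosome 1, 78101267 to 78196838) had the level given above, Pax7 (chromosome 4, 139737062 to 139833528) 23.02 ± 3.49 TPM, Lbx1 (chromosome 19, 45232688 to 45235811) 14.7 ± 2.55 TPM and Myf5 (chromosome 10, 107482908 to 107486134) 17.4 ± 3.07 TPM. Met, the receptor gene for the muscle guidance factor Hgf (chromosome 6, 17463800 to 17573980), stood at 11.6 ± 0.324 TPM, and Hgf itself (chromosome 5, 16553550 to 16619439) at 33.8 ± 4.76 TPM. Myod1 (chromosome 7, 46376474 to 46379092) and Myog (chromosome 1, 134290004 to 134292547) had the levels given with the regulators.

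The median level of the 80 CDH-linked genes lay above that of each of 10000 random lists matched on gene length, whose central 95% on the log2(TPM + 1) scale was 3.44 to 4.76 against 5.89 for the CDH genes. The regulators and the matrix genes also lay at the 100th percentile, and the signalling genes at 99.6. The random lists were drawn from all 21446 protein-coding genes, of which 63.4% were expressed, so a list made up of expressed genes would tend to rank high. With no other tissue and no background of expressed genes alone, the percentiles do not show a level particular to the folds. These percentiles describe 2 libraries and are not a test across animals, and 39 of the 80 genes also stand in other lists described here. Part of what links these genes to CDH comes from mouse work on the diaphragm, so the lists are not independent of the tissue.

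**Figure D2:**
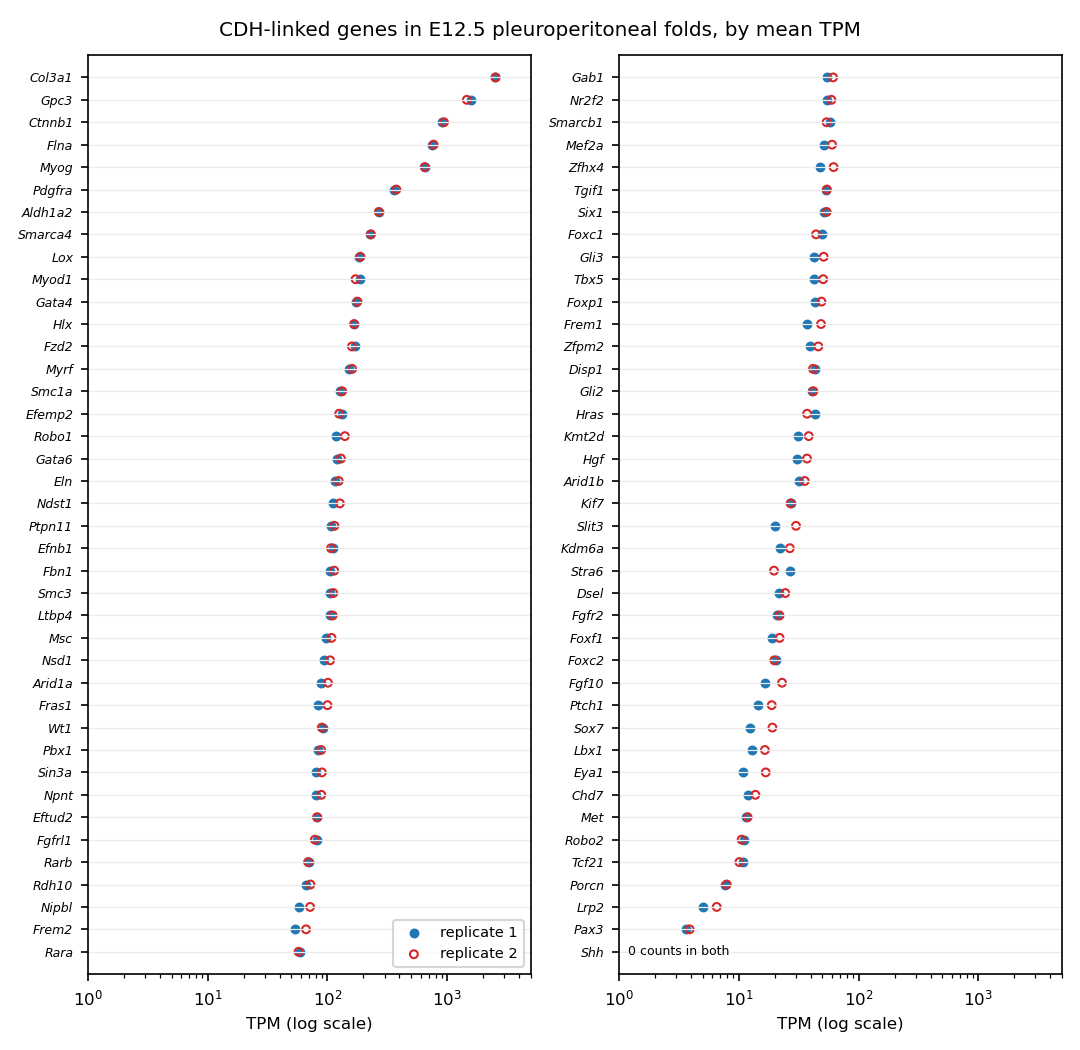
TPM (log scale) of the 80 CDH-linked genes in replicate 1 (filled points) and replicate 2 (open points), ordered by mean TPM down the left and then the right panel. Levels run from 2521 TPM for Col3a1 to 3.77 TPM for Pax3, and Shh had 0 counts in both libraries.

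The cell type lists ask which tissues the dissected folds held. All 34 muscle genes were expressed, with the median at the 100th percentile of random lists, and Actc1, Myog, Myh3 (542 ± 27.9 TPM) and Acta1 (516 ± 4.62 TPM) were highest, while Myf6 was lowest at 3.74 ± 0.480 TPM. All 34 fibroblast and mesenchyme genes were expressed as well (percentile 100), from Igf2, Col1a1, Col3a1 and Col1a2 (1321 ± 17.2 TPM) down to Osr2 (5.88 ± 2.22 TPM) and Ebf1 (2.19 ± 0.597 TPM). Mesothelial genes were expressed in 20 of 20 cases (percentile 94.2), led by Sulf1 at 343 ± 74.5 TPM, Aldh1a2, Upk3b at 231 ± 17.0 TPM and Podxl at 136 ± 1.47 TPM. Endothelial genes were expressed in 22 of 23 cases (percentile 83.1), led by the cadherin gene Cdh5 at 73.5 ± 12.1 TPM. The exception was Etv2, an early endothelial regulator, at 0.0562 ± 0.0795 TPM.

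Blood cell markers were detected. Of 22 erythroid genes, 21 were expressed in both libraries (percentile 89.7), and Hbb-y, Hba-a1 (554 ± 43.8 TPM) and Hbb-bs (476 ± 45.3 TPM) were highest. All 20 macrophage and leukocyte genes were expressed (percentile 99.4), led by the complement gene C1qb at 98.1 ± 1.83 TPM and Tyrobp at 81.2 ± 7.53 TPM. Of the neural crest and Schwann cell precursor genes, 13 of 14 were expressed (percentile 29.9), among them Ngfr at 109 ± 8.35 TPM, Erbb3 at 70.3 ± 7.85 TPM and Sox10 at 22.6 ± 2.20 TPM. Of 23 neuronal genes, 14 were expressed (percentile 9.81), led by the axonal growth gene Gap43 at 28.8 ± 6.21 TPM, and the motor neuron gene Mnx1 had 0 counts, which allows up to 0.180 TPM.

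Markers of neighbouring organs ranged widely in level. Each percentile sets a list against random lists of its own gene lengths, so percentiles do not rank the lists by level. Median levels were 3.91 TPM for hepatoblasts, 0.639 for lung and gut epithelium, 6.31 for cardiac muscle and 0.713 for mesonephros, gonad and adrenal. They were 5.38 TPM for cartilage, tendon and sclerotome and 1.07 TPM for surface ectoderm. Hepatoblast genes were expressed in 17 of 20 cases (percentile 62.1), with the fetal serum protein genes Afp (chromosome 5, 90490714 to 90508907) at 104 ± 64.5 TPM and Alb (chromosome 5, 90460889 to 90476603) at 69.8 ± 47.9 TPM. Of the lung and gut epithelial genes 8 of 20 were expressed (percentile 4.10), and Nkx2-1, a lung and thyroid regulator, had 0 counts, which allows up to 0.145 TPM. Id2 (122 ± 0.621 TPM) and Spint2 (42.9 ± 3.25 TPM) led that list, but Id2 also stands in the Bmp and Tgf-beta list. Cardiac genes were expressed in 14 of 20 cases (percentile 71.7). Tnni1 at 337 ± 5.95 TPM and Tnnt2 at 311 ± 15.7 TPM, which embryonic skeletal muscle also expresses, were highest, whereas the heart regulator Nkx2-5 stood at 0.174 ± 0.137 TPM. Mesonephros, gonad and adrenal genes were expressed in 7 of 20 cases (percentile 1.29), led by Sox9 at 31.1 ± 8.56 TPM and Emx2 at 14.3 ± 8.58 TPM. Sox9 also stands in the cartilage, tendon and sclerotome list. The lists of cartilage, tendon and sclerotome (15 of 20, percentile 8.49) and surface ectoderm (8 of 16, percentile 8.13) were led by the tendon regulator Scx at 132 ± 24.0 TPM and by the desmosome gene Dsp at 25.7 ± 1.81 TPM. Without replicate 1 the cartilage list lay at percentile 5.49, and without replicate 2 the mesonephros, gonad and adrenal list at 2.48.

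Among the pathway lists, retinoic acid genes were expressed in 20 of 21 cases (percentile 99.5), with Aldh1a2, Crabp2 at 268 ± 46.1 TPM and Crabp1 at 139 ± 59.1 TPM among the highest. Of the Hedgehog genes 14 of 17 were expressed (percentile 81.9): the coreceptor gene Gas1 stood at 256 ± 14.7 TPM and Smo at 166 ± 0.811 TPM. Wnt genes were expressed in 36 of 37 cases (percentile 93.4), with Ctnnb1, Sfrp1 at 591 ± 20.5 TPM and Sfrp2 at 369 ± 54.5 TPM highest and Wnt16 lowest at 0.185 ± 0.0828 TPM. All 24 Fgf and Hgf genes (percentile 95.8) and all 31 Bmp and Tgf-beta genes (percentile 99.6) were expressed, led by Fgfr1 at 126 ± 2.74 TPM and by Id3 at 348 ± 14.1 TPM. Axon guidance genes were expressed in 26 of 28 cases (percentile 99.96), led by Epha3 at 154 ± 15.3 TPM and Robo1. All 22 proliferation genes were expressed (percentile 100), from Mcm6 at 285 ± 18.5 TPM to Ccnb1 at 29.2 ± 0.109 TPM. Of the immediate early and heat shock genes 18 of 22 were expressed (percentile 84.2), with Jun at 147 ± 1.85 TPM and Fosb at 0.516 ± 0.152 TPM, and all 20 hypoxia response genes were (percentile 89.4), led by Aldoa at 598 ± 28.8 TPM. Of the sex-linked genes 5 of 8 were expressed (percentile 19.2). Xist, transcribed from the inactive X chromosome, stood at 172 ± 27.1 TPM and the Y-linked Ddx3y at 24.6 ± 3.79 TPM, both in each library.

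Hox genes, which are expressed in nested domains along the body axis, were compared by paralog group. Of the 38 Hox genes found in the files, 22 were expressed in both libraries: 9 of 11 in paralog groups 1 to 4, 6 of 6 in groups 5 to 6, 5 of 5 in groups 7 to 8 and 2 of 16 in groups 9 to 13. Hoxa5 (chromosome 6, 52201754 to 52204587) was highest at 157 ± 11.2 TPM, followed by Hoxc5 at 57.0 ± 4.71 TPM, Hoxc4 at 50.4 ± 3.45 TPM and Hoxb3 at 47.4 ± 6.76 TPM. The expressed genes of groups 9 to 13 were Hoxb9 at 5.91 ± 1.24 TPM and Hoxa9 at 3.89 ± 1.18 TPM, of which Hoxb9 alone had at least 5 TPM in both libraries. Of the most posterior genes, Hoxd12 and Hoxd13 had 0 counts in both libraries, which allows up to 0.158 and 0.166 TPM. Hoxb3 shares 52.9% of its exon bases with another annotated gene. As a list the Hox genes lay at percentile 36.0.

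**Figure D3:**
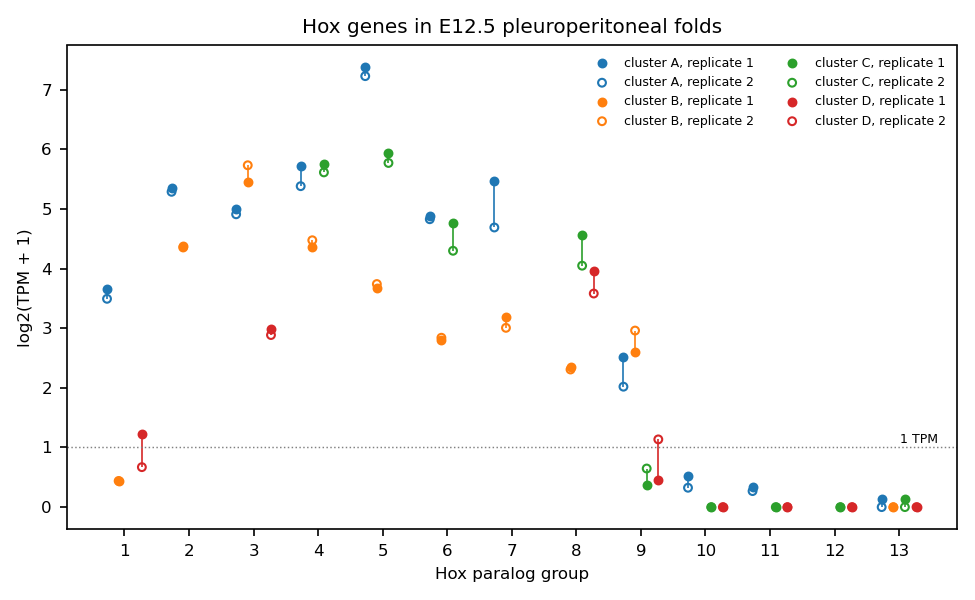
Level of each Hox gene as log2(TPM + 1) against its paralog group, coloured by cluster, in replicate 1 (filled) and replicate 2 (open), with a line joining the libraries and a dotted line at 1 TPM. Groups 5 to 8 lie above the dotted line in both libraries, and 2 of the 16 genes in groups 9 to 13 do.

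The comparison of the libraries asks how far dissections of the same tissue differed. Liver genes differed most as a group: of 20 hepatoblast genes 15 were higher in replicate 2, none lower, and 13 of these by at least 2-fold, with a median log2 ratio of 1.24. Afp had a log2 ratio of 1.32 (95% interval 1.21 to 1.42, exact binomial adjusted p = 2.11e-138), Alb of 1.49 (1.36 to 1.63, exact binomial adjusted p = 3.23e-113) and the lipoprotein gene Apob of 1.92 (1.51 to 2.37, exact binomial adjusted p = 1.69e-21). Neuronal genes were also higher in replicate 2, 11 of 19 with none lower and 5 by at least 2-fold (median 0.78), among them the noradrenaline synthesis gene Dbh at 2.01 and the RNA-binding protein gene Elavl3 at 2.54. Mesonephros, gonad and adrenal genes went the other way, with 6 of 15 lower in replicate 2, 5 of them by at least 2-fold, and 2 higher (median -0.53).

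In that list Emx2 (chromosome 19, 59458372 to 59465357), a urogenital regulator, had a log2 ratio of -1.35 (95% interval -1.60 to -1.10) and Amhr2 of -1.07. Pax8 (chromosome 2, 24420551 to 24475599), a nephric regulator, had 69 counts in replicate 1 and 3 in replicate 2, a ratio of -4.13 (-6.65 to -2.73). Lhx1 had 23 and 2 counts, a ratio of -3.05 (-6.47 to -1.32). Cdh16, a kidney cadherin gene, had 20 counts and 0, at least 5.87-fold lower in replicate 2 at the floor of 3 counts per library, and the list's median with Cdh16 at that bound was again -0.53.

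Erythroid genes had a median log2 ratio of 0.38, with 9 of 22 higher and 2 lower. Hbb-y, the most abundant of them, was lower in replicate 2 at -0.16. Hox genes were lower on balance, 10 of 28 lower and 1 higher (median -0.17): Hoxa7 had a ratio of -0.84 and Hoxb3 of 0.25. Of the 79 CDH-linked genes with enough counts, 30 were higher and 9 lower in replicate 2, none by 2-fold, with a median of 0.048 (0.022 once corrected for gene length and GC content). The largest ratios in size were those of Eya1 and Sox7, both 0.59, and Slit3, 0.54 (0.42 to 0.66, exact binomial adjusted p = 1.19e-17). Of the CDH sublists, the regulators had 15 higher and 3 lower (median 0.077, corrected 0.049), the signalling genes 9 and 3 (0.018, corrected -0.017) and the matrix genes 6 and 3 (0.072, corrected 0.054).

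Muscle genes had 9 of 34 higher and 1 lower in replicate 2 (median 0.094), with Ttn at 0.64, and fibroblast and mesenchyme genes had 12 higher and 10 lower (0.026), with Tbx4, a limb and lung mesenchyme regulator, at 1.38. Medians were 0.14 for endothelium (8 higher, 1 lower), 0.19 for neural crest and Schwann cell precursors (4 and 0), 0.15 for cardiac muscle (3 and 0; 0.075, inside the range of random lists, with members of at least 100 counts; corrected 0.22) and 0.22 for cartilage, tendon and sclerotome (5 and 3; corrected 0.14). They were 0.28 for sex-linked genes (3 and 0; 0.075, inside the range of random lists, once corrected for gene length and GC content), 0.15 for axon guidance (15 and 3; corrected 0.097), 0.096 for the Fgf and Hgf pathway (6 and 1) and -0.10 for the Wnt pathway (8 and 13; -0.047, inside that range, with members of at least 100 counts). These lists, with the hepatoblast, neuronal, erythroid, mesonephric and Hox lists, all CDH-linked genes and the CDH regulators, and apart from fibroblasts and mesenchyme, made up the 16 of 29 lists whose median lay outside the central 95% of random lists, where about 5% of lists of randomly drawn genes would. Genes of a marker list can vary together more than randomly drawn genes, so that share is no expectation for these lists. The other 13 lay inside. Besides the fibroblast list and the CDH signalling and matrix lists, these were mesothelium (median 0.0044, 4 higher, 2 lower), macrophages and leukocytes (-0.10, 0 and 3), lung and gut epithelium (-0.032, 0 and 1), surface ectoderm (0.11, 0 and 1) and the retinoic acid pathway (-0.066, 2 and 6). The last were the Hedgehog (-0.047, 2 and 1) and Bmp and Tgf-beta pathways (0.037, 6 and 4), proliferation (-0.024, 3 and 5), immediate early and heat shock genes (0.011, 1 and 3) and hypoxia response (-0.0097, 3 and 4).

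**Figure D4:**
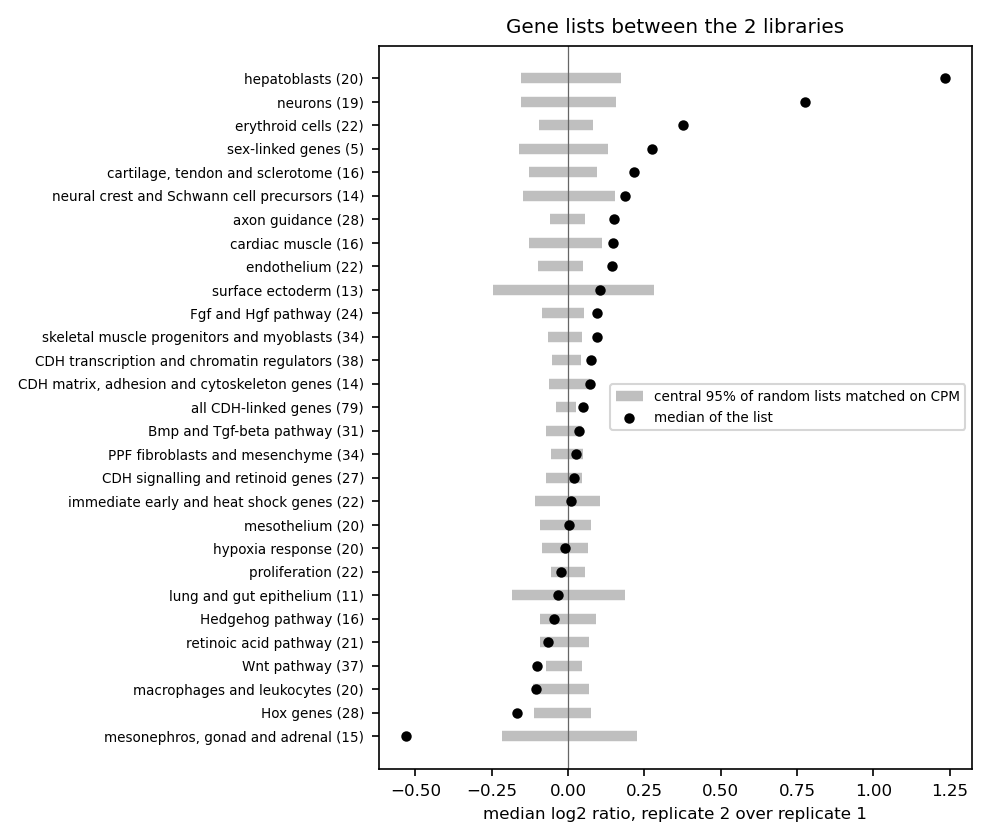
Median log2 ratio of replicate 2 to replicate 1 for each of 29 gene lists (points; members with at least 10 counts in parentheses) over the central 95% of 10000 random lists matched on CPM (bars). Hepatoblast genes (1.24) and neuronal genes (0.78) lie farthest to the right and mesonephros, gonad and adrenal genes (-0.53) farthest to the left.

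Among genes with an adjusted p under 0.05, at least 100 counts and a mean of at least 1 TPM, those with the highest ratios were the ribosomal protein pseudogenes Rps3a3 (6.33, 17 and 1238 counts) and Rpsa-ps10 (5.87, 18 and 952 counts), the DNA repair gene Neil2 (2.23), Hmgb2 (2.10), 2610507I01Rik (2.06), the pyruvate kinase gene Pklr (2.01), Dbh, Ret (1.96), Apob and Alb. The lowest ratios among the same genes were those of Foxd1, a regulator of kidney stroma (chromosome 13, 98354245 to 98356705), at -4.89 with 285 and 8 counts, Gm14078 (-3.38), the pseudogene Vcp-rs (-3.29), Adh1 (-1.70), S100a9 (-1.70), Gm12663 (-1.64), Gm5506 (-1.63), E330013P04Rik (-1.55), Avpr1a (-1.48) and Gm23935 (-1.46). The transcripts of Rps3a3, Rpsa-ps10 and Vcp-rs are 98.9%, 99.3% and 99.0% identical to those of Rps3a1, Rpsa and Vcp.

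Over all 19433 genes tested, 3346 had an adjusted p under 0.05 in the exact binomial test, 1691 higher and 1655 lower in replicate 2, and 223 of them differed by at least 2-fold, 125 higher and 98 lower. Of the 223, 154 were protein-coding and 59 of those were expressed in both libraries. The chi-square of the counts per gene was 6.25, and the edgeR common coefficient of biological variation was 7.99%. Counts of members higher and lower adjusted over the list alone were 15 and 0 for hepatoblasts, 14 and 0 for neurons, 2 and 8 for mesonephros, gonad and adrenal, 9 and 3 for erythroid cells, 2 and 10 for Hox genes, 33 and 11 for all CDH-linked genes and 14 and 1 for muscle. They were 17 and 4 for the CDH regulators, 9 and 4 for CDH signalling, 7 and 3 for CDH matrix genes, 13 and 10 for fibroblasts and mesenchyme, 4 and 2 for mesothelium, 9 and 1 for endothelium, 0 and 3 for macrophages, 4 and 0 for Schwann cell precursors, 3 and 0 for cardiac muscle and 8 and 3 for cartilage, tendon and sclerotome. For the lung and gut and the surface ectoderm lists no member passed. The pathway and control lists had 2 and 6 (retinoic acid), 2 and 1 (Hedgehog), 9 and 15 (Wnt), 7 and 1 (Fgf and Hgf), 7 and 5 (Bmp and Tgf-beta), 15 and 4 (axon guidance), 4 and 6 (proliferation), 1 and 3 (immediate early and heat shock), 4 and 4 (hypoxia) and 3 and 0 (sex-linked). Across 12266 protein-coding genes the ratio followed gene length, with a Spearman rho of 0.39. The binomial test covers counting error only: with a spread of 7.99% added to simulated counts, 4403 unchanged genes had an adjusted p under 0.05 and 41 passed 2-fold as well. That spread was a single value for all genes, estimated from these same 2 libraries with their differences included. The simulation gave more genes past the adjusted p than the 3346 of the data, so it is no exact gauge of the observed calls. With at least 100 counts required, 71 genes differed by 2-fold.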

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

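Tests with TPM rescaled without features under 200 bp, without short features and pseudogenes, without CDH genes that share over 25% of their exon bases, with random lists matched on gene length and CPM, and with ratios corrected for gene length and GC content were chosen only after the result was seen. Of the 80 CDH-linked genes, 79 were expressed under each alternative run except at 5 TPM (78), and their median stayed at the 100th percentile under all 8 alternatives run. A percentile at its ceiling cannot show how far the median moved, and no background of expressed genes alone was among the alternatives. Expressed protein-coding genes ranged from 11385 at 5 TPM to 14379 at 10 counts in both libraries. No list median outside the range of random lists changed sign between the libraries. List medians inside that range that changed sign were CDH signalling (0.018 to -0.017 with the correction for length and GC), immediate early and heat shock genes (0.011 to -0.046) and hypoxia response (-0.0097 to 0.0017), the last pair with members of at least 100 counts. Among 574 named gene ratios, 5 crossed the adjusted p threshold with DESeq2 size factors (3 gained, 2 lost) and 6 with library size alone (2 gained, 4 lost). These scalings shift all genes alike by a small amount, so they say little about the direction of single genes, for which no other alternative was run.

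At 5 TPM in both libraries, fewer genes were expressed among erythroid cells (12), Schwann cell precursors (7), neurons (8), hepatoblasts (7), lung and gut (5), mesonephros, gonad and adrenal (4), surface ectoderm (3) and Hox groups 9 to 13 (1), since a higher threshold can only lower a count. Without replicate 1 or replicate 2, level percentiles ranged from 93.92 to 94.35 for mesothelium, 99.44 to 99.53 for macrophages, 29.03 to 32.6 for Schwann cell precursors, 1.3 to 2.48 for mesonephros, gonad and adrenal, 99.225 to 99.495 for Bmp and Tgf-beta, 99.88 to 99.99 for axon guidance and 80.9 to 84.91 for immediate early genes. They ranged more widely for hepatoblasts (50.09 to 72.71), erythroid cells (86.51 to 95.13), neurons (7.12 to 13.675) and cartilage, tendon and sclerotome (5.49 to 9.97). The ratio between libraries has no such alternative.

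Genes differing by 2-fold numbered 71 at 100 counts (39 higher, 32 lower in replicate 2). They numbered 429 at 1.5-fold (243 and 186) and 101 at 3-fold (57 and 44), which follows from the threshold. With members of at least 100 counts, the CDH matrix median (0.072) passed the bound of random lists, and the cardiac (0.075) and Wnt (-0.047) medians no longer did. With the correction for length and GC, the CDH matrix (0.054), macrophage (-0.11) and Bmp and Tgf-beta (0.049) medians passed it and the sex-linked median (0.075) no longer did. Bmp and Tgf-beta (0.037) also passed it when lists were matched on length and CPM. That median was 0.037 in the main setting too, and the CDH matrix median at 100 counts was also the main one, 0.072. In these cases the random range differed and not the list median. The cause of the other changes was not tested. TPM without short features moved 363 of 642 named gene levels by more than their SD, by a common factor in each library. No paired analysis was possible because there is a single group.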

Other observations

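The independent lists of liver and nephric genes, the correction for length and GC content and the search for copies were tests of patterns already seen, with the outcomes to expect written down before each was run; the pair sums, the count of copies that went the opposite way and the reading of the nephric test were chosen only after the result was seen. Besides the neuronal genes described, the choline transporter gene Slc5a7 (85 and 178 counts, log2 ratio 1.25), the vesicular monoamine transporter gene Slc18a1 (34 and 73 counts, 1.28) and the synaptic vesicle gene Syp (40 and 78 counts, 1.14) were at least 2-fold higher in replicate 2, all named after their values were seen. Lower in replicate 2 by at least 2-fold were Il33 (818 and 304 counts, -1.24), Abi3bp (714 and 281, -1.16), Bmp3 (187 and 65, -1.33), Fzd10 (96 and 31, -1.43) and the mast cell protease gene Cpa3 (91 and 29, -1.45). The antisense transcript Emx2os (-1.32) had a ratio close to that of Emx2 (-1.35), which shares 8.79% of its exon bases with it, and reads were assigned on either strand.

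Across 12266 protein-coding genes the ratio of the libraries followed gene length (Spearman rho 0.39 across genes) and GC content (-0.21), with medians from -0.099 in the shortest genes, of median length 1597 bp, to 0.074 in the longest, of 8477 bp. Genes are not independent replicates. The trend is of the size of several list medians: with its removal the median went from 0.048 to 0.022 for all CDH-linked genes, from 0.077 to 0.049 for the CDH regulators, from 0.15 to 0.097 for axon guidance and from 0.28 to 0.075 for sex-linked genes, of which the last alone then lay inside the range of random lists.

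Hepatoblast genes were higher in replicate 2, with Afp at 58.5 and 150 TPM and Alb at 35.9 and 104 TPM. A trend on gene length or GC content is argued against as the whole cause, because the list's median was 1.304 after its removal, above the range of random lists. A larger share of liver tissue in replicate 2 may contribute. Of 33 hepatocyte genes written down without looking at their values, the 23 with at least 10 counts over both libraries had a median log2 ratio of 0.5765. That lay above the central 95% of random lists, which ended at 0.28, with 6 genes higher, none lower and 17 not past the threshold. The 23 genes stood at low levels, with medians of 0.585 TPM in replicate 1 and 0.915 TPM in replicate 2, where 11 reached 1 TPM. As with the other lists, genes of one tissue can vary together more than randomly drawn genes. Apoc1 (-0.29), Cps1 (-0.31), Hpx (-0.060) and Apoh (-0.042) were among the 7 not above 0. Expression of these genes within the folds, and a biological difference between the embryos, were not tested and stay open, as does the dissection, in which no step named by the labels removes the liver.

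Mesonephros, gonad and adrenal genes were lower in replicate 2, and their median was -0.6107 after the trend on length and GC content was removed, which argues against that trend as the whole cause. Nephric tissue in replicate 1 is a hypothesis that could not be decided. Of 26 nephric genes written down without looking at their values, the 19 with at least 10 counts over both libraries had a median log2 ratio of 0.06279. This median lay inside the range of random lists (-0.18 to 0.20). That met the outcome written beforehand as counting against this explanation. It is read here as undecided, a reading adopted after the value was seen, because the called members went both ways, among them Foxd2 (-1.44) lower and Cdh6 (0.50) and Mecom (0.40) higher, and genes such as Six2 (33.2 and 29.2 TPM) stood at levels that folds may reach on their own. The strongest members, Pax8, Lhx1, Cdh16 and Emx2, were not tested apart from the list, and no biological explanation was tested.

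Some features that differed by 2-fold or more may do so because reads were divided between near-identical sequences. With at least 100 counts and a known sequence, 14 of 60 such features had another gene's transcript at 95% identity or more over at least 50% of their length, against 608 of 13137 others (odds ratio 6.272, 95% interval 3.17 to 11.7, two-sided Fisher's exact test p = 5.35e-07). Several of the 60 had been seen before the test, and 12 of the 14 were processed pseudogenes, which have a copy by nature. In 7 of the 14 the copy differed the opposite way, in 1 the same way and in 6 it did not pass the threshold. The copy that differed the same way was Xist, paired with Gm26992, whose exons overlap those of Xist. Genes at the same locus were not left out of the search. The odds ratio, these counts and the sums below can therefore include overlapping annotation. Summed with the copy, 11 of the 14 log2 ratios lay between -0.35 and 0.30, Vcp-rs with Vcp (0.0066) and Rps3a3 with Rps3a1 (0.24) among them. In 8 of the 11, however, the copy had at least 5 times the counts and so set the sum. Rpsa-ps10 with Rpsa (2.29), Gm6472 with Rps7 (-1.03) and Gm11223 with Stmn1 (-0.72) stayed apart. Outside the tested set, Gm5506 (394 and 112 counts, -1.63) summed with Eno1 gave 3485 and 4389 counts. That ratio of 0.52 was opposite in sign to Gm5506 and set mostly by Eno1. A strain variant between the 129 and C57BL/6 alleles was not tested.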
